A study of Mus musculus with 6 samples.

How the data were processed

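Libraries were made with the SMART-Seq mRNA LP kit (Takara) from RNA of sorted Lin-CD117+ bone marrow cells, per the labels' protocols. Reads were aligned with STAR to the mm10 mouse genome, per the submitters' processing notes; the STAR version is not given in the sources used here. The deposited values are raw counts of read pairs per gene, made with featureCounts 2.0.3 over exons of the UCSC mm10 gene annotation, per the file headers. The recorded command sets no strand option, so reads of a gene and of an antisense partner cannot be told apart. It also sets no option for reads that map to several places or to several genes, so by the tool's defaults such pairs were left out. Genes with near-identical copies are therefore uncertain, such as Ifit3 and Ifit3b, the Oas1 genes, Bcl2a1 genes and alpha and beta globins; Hba-a1 and Hbb-bs held 0 counts in every pool. The table holds 24421 gene symbols and 0 mitochondrially encoded genes. It also gives each gene's summed exon length in bases, a deposited value used for checks of length.

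Each column was matched to its pool by the library name in the labels, and the labels' treatment gave the group: 3 untreated pools (1 to 3) and 3 RUX pools (4 to 6). The pools came from different mice, 2 to 3 per pool, so p-values measure the spread between pools. Pool numbers are not shared between groups and nothing pairs them. The labels name no batch. Totals were 27354768 to 48747137 read pairs. The 2 transcripts Lars2 and Rn45s, the second a ribosomal RNA precursor, took 1.39 to 6.25% of the counts per pool, and the 10 most abundant genes 4.48 to 9.66%. Reads were PCR-amplified without stated molecular identifiers, so floors (3 counts of the total) cover counting error only.

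From the counts, edgeR 4.0.16 in R 4.3.3 kept 13411 genes with filterByExpr at its defaults, which removed under 0.04% of the counts of any pool, and scaled libraries by TMM (factors 0.938 to 1.035). Genes were tested by the two-sided quasi-likelihood test without robust fitting, with treatment as the only term, and p was adjusted by Benjamini-Hochberg over the tested genes at a threshold of 0.05. CPM values are relative to the TMM-scaled library of tested genes, except those of sort antigens and sex-linked genes, which are relative to the whole library. Log2 fold changes are RUX minus untreated; the SE was derived from the fold change and its F value, and 95% intervals from that SE.

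The 26 gene lists (14 pathways and 12 sets of cell type markers) were fixed before the data were examined. So were the 7 lists of first interest among them, the tests, the rule for named genes and most alternatives. First interest covered the STAT5/STAT3 target, type I interferon, interferon-gamma, stem cell, erythroid, S-phase and G2/M lists. Of the listed genes, 9 were not found by symbol in the table and are not analysed here. Lists were tested by camera on the edgeR fit with a preset correlation of 0.01, two-sided, adjusted over the 26 lists, and beside it with the correlation estimated from the pools and by fry. Camera compares a list with other genes, whereas fry tests the list's genes alone, on balance in one direction or, in its mixed form, in either direction; the mixed form also called 0 lists (smallest adjusted p = 0.891). With an estimated correlation 0 of the 7 calls held. Of these 7 called lists, only the type I interferon and stem cell lists were of first interest. Per-pool list values are mean deviations of log2(CPM + 1) from each gene's mean over the 6 pools, compared by a two-sided exact permutation test; 3 against 3 pools cannot give a p below 0.1.

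The rule named the genes with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between groups; as 0 passed, it took the 5 with the smallest unadjusted p in each direction, given as values. It also took up to 4 members of each list by unadjusted p, and always Jak1, Jak2, Stat3, Stat5a, Stat5b, Cish, Socs1, Socs2, Socs3, Pim1 and Kit. Genes with symbols of predicted or unnamed loci were left out, and a few genes that the rule takes are not reported here. Coordinates are 1-based from the deposited annotation in mm10, from the first to the last exon of a gene.

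Alternatives changed one choice at a time: DESeq2 size factors or upper-quartile scaling in edgeR, no low-count filter, at least 1 CPM in 3 pools, robust fitting, DESeq2 1.42.0, limma-voom 3.58.1 without and with quality weights, removal of 10 hemoglobin and 79 ribosomal protein genes (0 and 78 of them among the tested genes, so the hemoglobin part changed nothing), each pool left out in turn, an adjusted p under 0.01, a minimum fold of 1.5 and the other list tests. For lists, a change of direction was read from camera and counted only where a call was made in either setting. Robust fitting does not enter camera, and DESeq2 gave list medians only. Added after the data had been seen were fits without untreated pool 3 and RUX pool 4, with 1 surrogate variable (sva 3.50.0), and without Lars2 and Rn45s.

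The tests were first run on simulated counts for the 13411 genes, with independent genes, the means and library sizes of the 6 pools and 200 changed genes in each of 5 simulations. For this comparison edgeR recovered 22.2% of 1.5-fold, 66.0% of 2-fold and 93.0% of 4-fold changes at an adjusted p under 0.05 and called 0.09% of unchanged genes. DESeq2 recovered 30.9, 69.6 and 93.0% and limma-voom 21.0, 64.8 and 92.7% of the same fold sizes. A list shifted by 0.5 on the log2 scale was called in 5 of 5 simulations by camera with either correlation and by fry. Simulated genes did not vary together, so these shares do not cover variation shared between genes of a list.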

Results

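RNA was sequenced from Lin-CD117+ cells of CByB6F1 mouse bone marrow, a fraction that lacks lineage antigens, carries the KIT receptor and holds hematopoietic stem and progenitor cells. The 6 libraries were pools of cells, 3 from untreated mice (pools 1 to 3) and 3 from mice given ruxolitinib (RUX, pools 4 to 6), an inhibitor of the JAK1 and JAK2 kinases that relay cytokine and interferon signals. Each pool combined cells of 2 to 3 mice of one group, labelled female and 2 to 5 months old. The dose, length of treatment and time since the last dose are not given in the sources used here. Counted read pairs totalled 27354768, 38691826 and 37360937 in untreated pools 1, 2 and 3 and 46027491, 47730958 and 48747137 in RUX pools 4, 5 and 6, so the untreated libraries were the shallower ones.

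The pools resembled each other as much across treatment as within it. Pearson's r of log2(CPM + 1) over 13411 genes was 0.9864 to 0.9941 for the 6 pairs within a group and 0.9866 to 0.9937 for the 9 pairs between groups, computed across genes, which are not independent replicates. All pairs differed by far more than sampling noise, with chi-square values per degree of freedom of at least 36.3, so none was a duplicate library. The first principal component held 39.7% of the variance and placed untreated pool 3 (24.1) and RUX pool 4 (19.4) apart from the other 4 pools (−16.5 to −3). The genes with the highest loadings on it, chosen after their values were seen, included Prg2, which encodes eosinophil major basic protein, and S100a8 and S100a9, which encode calprotectin of neutrophils and monocytes. Prg2 stood at 214 and 207 CPM in untreated pool 3 and RUX pool 4 and at 35.7 to 80.7 CPM in the other 4 pools.

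**Figure D1:**
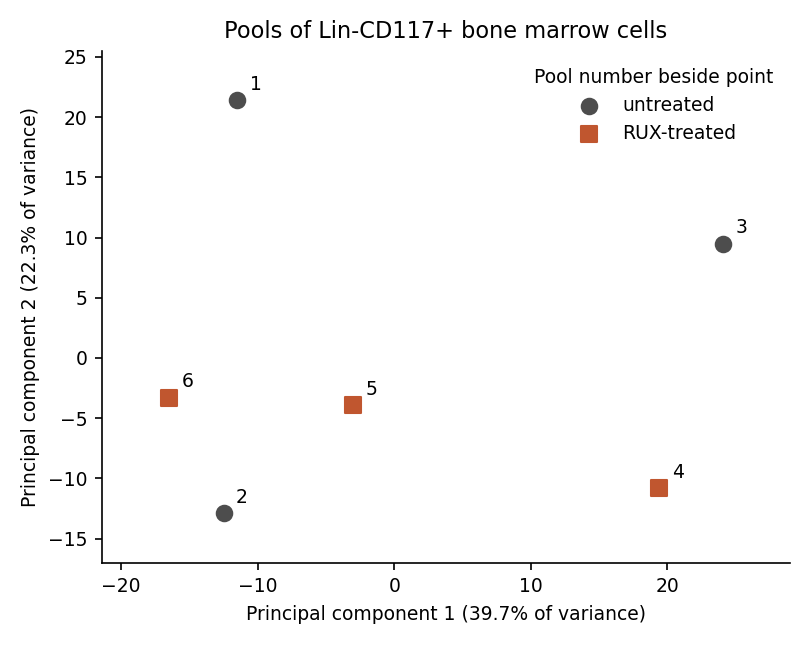
Scores of the 6 pools on the first and second principal components of log2(CPM + 1), which held 39.7% and 22.3% of the variance; circles are untreated pools 1 to 3 and squares are RUX pools 4 to 6. Untreated pool 3 and RUX pool 4 lie at the right, and neither axis separates the treatments.

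The study asked how ruxolitinib alters the transcriptome of these cells in normal mice. No single gene passed the test between RUX and untreated pools, while small shifts were shared across some gene lists. Type I interferon-stimulated genes and hematopoietic stem cell markers were the lists with the smallest p on the higher side, with median folds of 1.16 and 1.17. Markers of lymphoid, T and NK, and monocyte and dendritic cells lay lower, with median folds of 0.91, 0.89 and 0.92. None of these list results held once the correlation among the genes of a list was estimated from the 6 pools.

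Of 24421 genes in the table, 13411 were tested by edgeR's quasi-likelihood test and 0 had a Benjamini-Hochberg adjusted p under 0.05. DESeq2 and limma-voom also gave 0. At an unadjusted p under 0.05 there were 254 genes (114 higher and 140 lower with RUX), or 1.89% of those tested. The share by chance is 5%, or 671 genes. DESeq2 gave 281 and limma-voom 262 genes. Other ways to split the 6 pools 3 against 3 gave 135 to 1810 genes in edgeR, on both sides of 671. A share under 5% is therefore no evidence that treatment had no effect. The 3 RUX values lay entirely above the 3 untreated values for 401 genes and entirely below for 436, together 6.24% against 10% by chance. The 95% interval of the fold change lay within 2-fold in either direction for 10847 genes (80.9%) and within 4-fold for 12927 (96.4%). Without the low-count filter 14 genes were called (4 higher, 10 lower). The 10 lower ones were all members of the neutrophil list (Retnlg, Lcn2, S100a8, S100a9, Chil3, Camp, Ngp, Ltf, Mmp8 and Mmp9), with log2 fold changes of −1.07 to −0.69; the 4 higher ones were the ribosomal RNA precursor Rn45s (0.90), the basophil protease gene Prss34 (1.19), Anp32a (0.79) and Lepr (3.14). With the filter the unadjusted p of the 10 was 0.0599 to 0.299. Genes of the 14 outside the naming rule are named after their values were seen. Limma-voom with quality weights called 1 gene, Cdkl2, which had 8 to 11 counts in each untreated pool and 0, 0 and 1 in the RUX pools.

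Among genes reaching a mean of 5 CPM without overlap between groups, those nearest to the threshold differed by less than 2-fold. The 5 with the smallest unadjusted p on the higher side were Slc15a4, Oasl2, Celsr1, Parp14 and Lrrc8a. Slc15a4, a histidine and peptide transporter of endolysosomes, measured 22.4 to 26.3 CPM in the 3 untreated and 34.3 to 37.8 CPM in the 3 RUX pools, a log2 fold change of 0.54 ± 0.15 (SE) with an edgeR adjusted p of 1. Celsr1, a cadherin of planar cell polarity, had a log2 fold change of 0.78 ± 0.24 (SE), and Lrrc8a, a subunit of the volume-regulated anion channel, one of 0.57 ± 0.20 (SE). On the lower side were Efcab7, Zfp946, Gpcpd1, March7 and Kcng1. Efcab7, a ciliary protein gene, measured 9.24 ± 2.45 CPM in untreated and 4.92 ± 0.269 CPM in RUX pools (mean ± SD, n = 3, as in all such pairs that follow), a log2 fold change of −0.91 ± 0.24 (SE). March7, which encodes a ubiquitin ligase, measured 69.9 ± 15.4 and 46.0 ± 2.89 CPM, a log2 fold change of −0.60 ± 0.17 (SE). The zinc finger gene Zfp946, the phosphodiesterase gene Gpcpd1 and the potassium channel subunit gene Kcng1 had log2 fold changes of −0.77, −0.67 and −0.67. All 10 had an edgeR adjusted p of 1, and each kept its direction in the alternative settings. In mm10, Slc15a4 spans 127595666 to 127617392 on chromosome 5, Efcab7 spans 99829500 to 99912783 on chromosome 4 and March7 spans 60209936 to 60248385 on chromosome 2, from first to last annotated exon.

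The Jak and Stat genes named here differed little between the groups, and no gene of the inhibited pathway passed the test. Jak1 (chromosome 4, 101151974 to 101265282) measured 254 ± 30.1 CPM in untreated and 255 ± 52.2 CPM in RUX pools, with a log2 fold change of 0.01 ± 0.17 (SE). Jak2 (chromosome 19, 29251803 to 29313080) measured 83.5 ± 17.9 and 74.2 ± 10.4 CPM, a log2 fold change of −0.17 ± 0.18 (SE). The signal transducers Stat3, Stat5a and Stat5b had log2 fold changes of 0.10, −0.15 and −0.10. Of the genes that STAT proteins induce as feedback, Cish measured 3.80 ± 0.462 and 5.59 ± 0.679 CPM without overlap, a log2 fold change of 0.55 ± 0.23 (SE; edgeR adjusted p = 1), and Socs1, Socs2 and Socs3 had values of 0.77, 0.38 and −0.04. The kinase gene Pim1 was at 37.3 CPM in untreated and 37.4 CPM in RUX pools. Of 22 measured STAT5/STAT3 target and feedback genes, 11 had positive and 11 negative log2 fold changes. Their median was −0.02, their mean 0.06 and the direction of camera, a test of a list against all other genes, was higher, at an adjusted p of 0.463; without RUX pool 6 the median was 0.08 and the adjusted p 0.0311. The 34 cytokine receptor, JAK and STAT genes had a median of 0.02, a mean of 0.05 and a camera adjusted p of 0.530, with Ghr and Csf2rb2 among the members without overlap on the higher side. Directions of Jak1, Pim1, Socs3, Stat5b and Kit were not the same in all alternatives.

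Type I interferon-stimulated genes lay higher with RUX as a list. Of 47 measured members, 39 had positive and 8 negative log2 fold changes, with a median of 0.22. Oasl2, an interferon-induced antiviral gene on chromosome 5 (114896934 to 114912245), measured 7.86 ± 1.06 CPM in untreated and 12.8 ± 2.67 CPM in RUX pools, a log2 fold change of 0.71 ± 0.21 (SE). Parp14, an ADP-ribosyltransferase gene on chromosome 16 (35832878 to 35871382), measured 12.9 ± 1.32 and 19.4 ± 3.72 CPM, a log2 fold change of 0.59 ± 0.19 (SE). Oas3, an oligoadenylate synthetase gene, had a log2 fold change of 0.69 and the interferon-induced Rtp4 one of 0.49. The list passed camera with a preset correlation (adjusted p = 1.29e-08), but not with an estimated correlation (adjusted p = 0.641) nor in fry (adjusted p = 0.948), which asks whether a list's genes move one way on balance. No member passed when adjusted over the list alone (0 genes, smallest adjusted p = 0.162) or over all genes (0). Mean deviations of the list per pool were −0.13 to −0.06 in untreated and −0.01 to 0.22 in RUX pools, without overlap; the two-sided exact permutation p was 0.1, the smallest that 3 against 3 pools allow, and 0.975 when adjusted over the lists. The 40 interferon-gamma and antigen presentation genes had a median of 0.02, a mean of −0.004 and a camera adjusted p of 0.717. Irf8, the transcription factor of monocyte and dendritic lineages (chromosome 8, 120736358 to 120756692), stood in that list at a log2 fold change of −0.43 ± 0.18 (SE; adjusted p = 1).

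**Figure D2:**
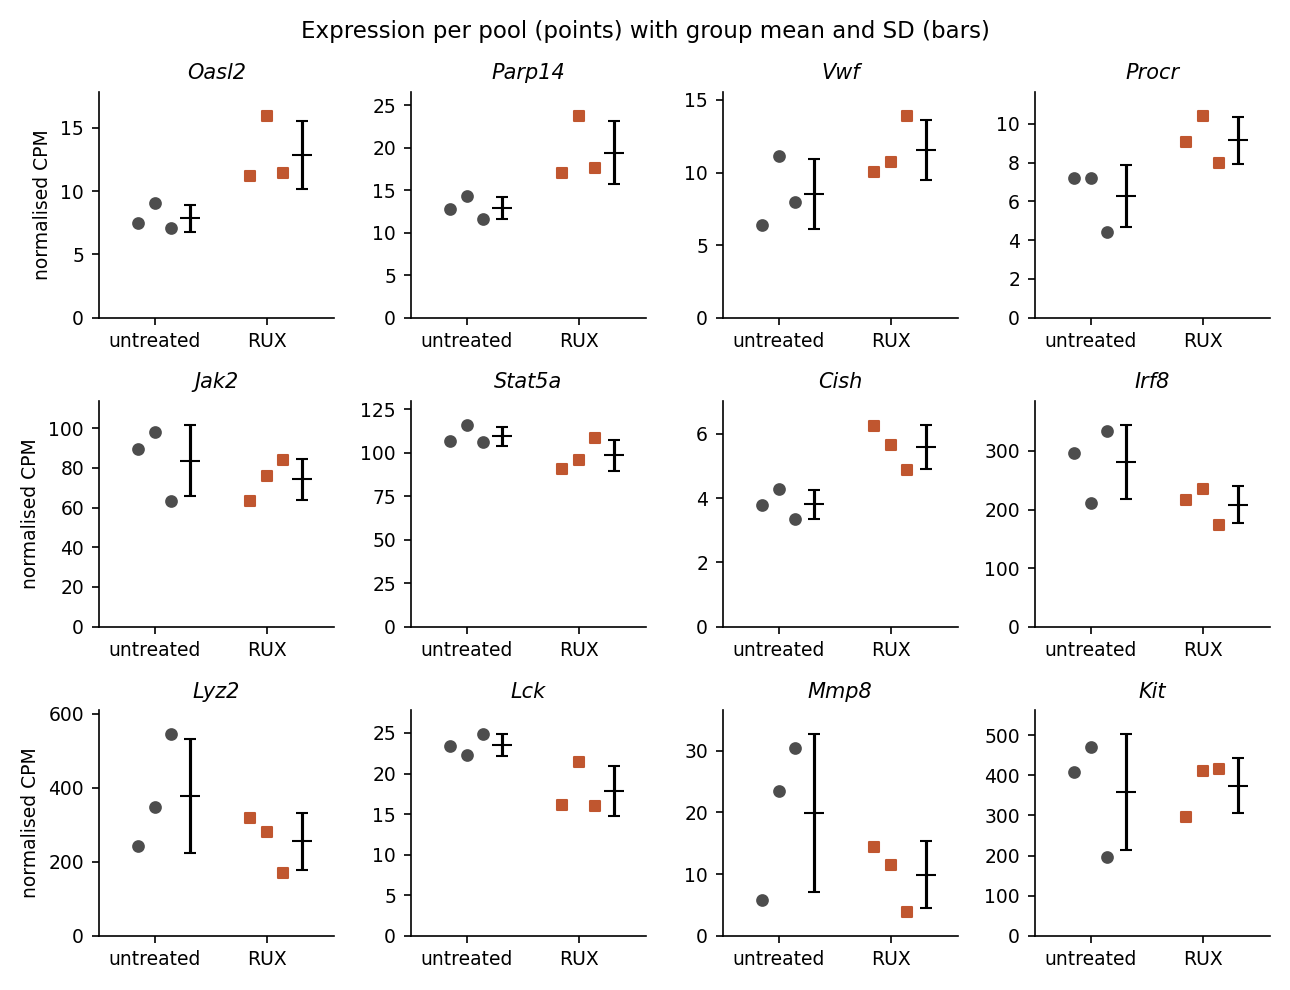
Normalised CPM of 12 genes in each pool, with circles for untreated pools 1 to 3, squares for RUX pools 4 to 6, and bars for the group mean and SD; every vertical axis is linear and starts at 0. Oasl2, Parp14, Procr, Cish and Lck show no overlap between groups, while Jak2, Kit and Mmp8 overlap widely, and every one of the 12 genes had an adjusted p of 1.

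Hematopoietic stem cell markers and megakaryocyte markers also lay higher with RUX as lists by camera with the preset correlation. The exact permutation p of the per-pool values was 0.2 for each list. Of 29 stem cell markers, 25 had positive log2 fold changes, with a median of 0.22. Procr, the protein C receptor gene that marks stem cells (chromosome 2, 155751217 to 155755478), measured 6.28 ± 1.61 CPM in untreated and 9.14 ± 1.21 CPM in RUX pools, a log2 fold change of 0.54 ± 0.23 (SE; adjusted p = 1). Vwf, the von Willebrand factor gene, measured 8.50 ± 2.42 and 11.5 ± 2.05 CPM, a log2 fold change of 0.44 ± 0.23 (SE; adjusted p = 1). The list passed camera with the preset correlation (adjusted p = 5.27e-07) and not with an estimated correlation (adjusted p = 0.641). It rested on untreated pool 3, whose mean deviation was −0.38 where the other 5 pools had −0.01 to 0.16. That pool was also the highest of the 6 for neutrophil (0.94), eosinophil (0.62) and monocyte and dendritic markers (0.33) and the lowest for Kit (191 CPM of the whole library); without it the median was 0.06 and the adjusted p 0.0871. Of 27 megakaryocyte and platelet markers, which share Vwf with the stem cell list, 22 had positive log2 fold changes, with a median of 0.09 and a mean of 0.17 (adjusted p = 0.0113; adjusted p = 0.641 with an estimated correlation). Tubb1, the platelet tubulin gene, was at 0.263 ± 0.134 and 0.674 ± 0.140 CPM. That call was lost without untreated pool 3 (median 0.02, adjusted p = 0.234) and without RUX pool 5 (median 0.04, adjusted p = 0.0686), and also, with medians of 0.09 and 0.12, with no low-count filter (adjusted p = 0.0885) and without untreated pool 3 and RUX pool 4 together (adjusted p = 0.22). Without RUX pool 4 or RUX pool 6 the median was 0.16 or 0.14.

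**Figure D3:**
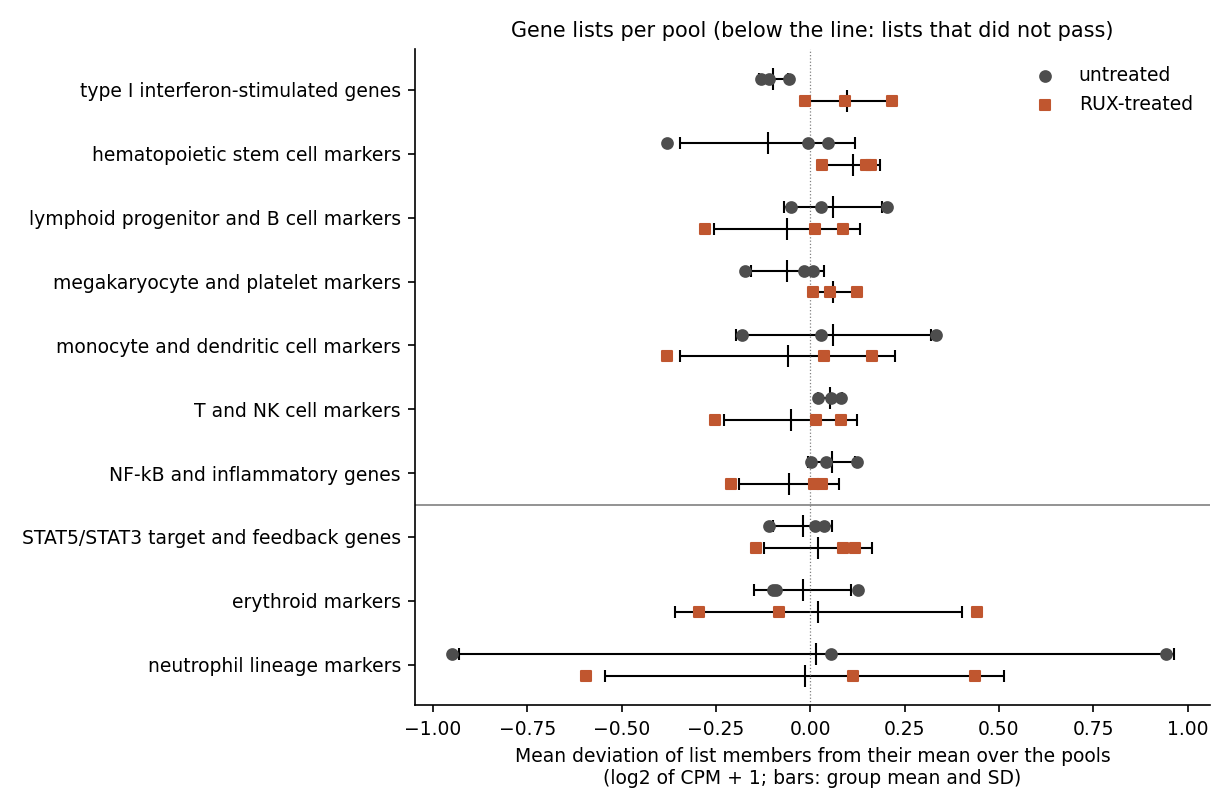
Mean deviation of each list's genes from their mean over the 6 pools, in log2(CPM + 1), with circles for untreated pools, squares for RUX pools, and bars for the group mean and SD. The upper 7 lists passed camera with the preset correlation; in the interferon list all 3 RUX pools lie above all 3 untreated pools, and in the other 6 the groups overlap or meet.

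Lymphoid and monocyte lineage markers and inflammatory genes lay lower with RUX as lists by camera with the preset correlation. Their per-pool values overlapped between the groups. The exact permutation p was 0.5 for lymphoid, 0.4 for T and NK, 0.7 for monocyte and 0.3 for NF-kB lists. Of 32 lymphoid progenitor and B cell markers, 26 had negative log2 fold changes, with a median of −0.14 (camera adjusted p = 0.00921; adjusted p = 0.914 with an estimated correlation). Dntt, which adds nucleotides at antigen receptor junctions, measured 534 ± 56.0 and 438 ± 51.0 CPM, and Satb1, a chromatin organiser of lymphoid cells, 98.6 ± 12.6 and 80.6 ± 9.87 CPM. Of 25 T and NK cell markers, 16 were negative, with a median of −0.16 (adjusted p = 0.0370; adjusted p = 0.914 with an estimated correlation). Tcf7, a transcription factor of early T cells, had a log2 fold change of −0.54 ± 0.21 (SE), and the T cell kinase gene Lck one of −0.40 ± 0.17 (SE). Of 32 monocyte and dendritic cell markers, 22 were negative, with a median of −0.13 (adjusted p = 0.0235; adjusted p = 0.914 with an estimated correlation), and Lyz2, encoding lysozyme, measured 378 ± 154 and 255 ± 77.5 CPM. Of 26 NF-kB and inflammatory genes, 17 were negative, with a median of −0.08 and a mean of −0.22 (adjusted p = 0.0471; adjusted p = 0.641 with an estimated correlation), and the chemokine genes Ccl3 and Ccl4 had log2 fold changes of −0.64 and −0.71. Cxcl2, the chemokine gene with the smallest unadjusted p of that list, was counted near the floor, at 0.866 ± 0.700 CPM in untreated and 0.208 ± 0.0745 CPM in RUX pools without overlap, a log2 fold change of −2.05 ± 0.64 (SE; adjusted p = 1). RUX pool 6 was the lowest pool on all 4 lists, at −0.28, −0.25, −0.38 and −0.21, and without it none was called (medians −0.01, 0.04, 0.01 and −0.11). None of the 4 was called with limma-voom quality weights (medians −0.11, 0.03, 0.01 and −0.05). The same held with 1 surrogate variable (medians −0.05, 0.04, −0.02 and −0.12). That variable was 0.903 in RUX pool 6 and −0.287 to −0.093 in the others, so it is no check separate from leaving out RUX pool 6. The lymphoid call was also lost without untreated pool 2 (median 0.01), the monocyte call without untreated pool 3 (median 0.01), and the T and NK and NF-kB calls without untreated pool 2 (medians −0.28 and −0.12) and without untreated pool 3 (medians −0.18 and −0.05). The T and NK and NF-kB calls were lost as well with at least 1 CPM in 3 pools (medians −0.17 and −0.06, adjusted p = 0.13 and 0.132) and limma-voom (medians −0.17 and −0.09, adjusted p = 0.061 and 0.0719), and the NF-kB call with no low-count filter (median −0.05, adjusted p = 0.063). Without untreated pool 3 and RUX pool 4 together the T and NK, NF-kB and monocyte calls ended (medians −0.34, −0.05 and −0.11, adjusted p = 0.0533, 0.0814 and 0.263) and the lymphoid call held (median −0.24). Other medians that moved by over 1.5 times with 1 pool left out, where the call held, were −0.39 and −0.27 for T and NK markers without RUX pool 5 and RUX pool 4, −0.12 and −0.12 for NF-kB genes without untreated pool 1 and RUX pool 4, and −0.23 and −0.28 for monocyte and dendritic markers without untreated pool 2 and RUX pool 4.

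Erythroid and granulocyte markers varied more between pools of a group than between the groups. Of 35 erythroid markers, 26 had positive log2 fold changes with a median of 0.05 (camera adjusted p = 0.270), and the list's mean deviation ran from −0.30 in RUX pool 4 to 0.44 in RUX pool 6. Klf1, the erythroid master regulator, measured 210 ± 30.1 and 246 ± 68.8 CPM. The 31 neutrophil lineage markers had a median of −0.08 and a mean of −0.31 (adjusted p = 0.722) and mean deviations from −0.95 in untreated pool 1 to 0.94 in untreated pool 3. Mmp8, a neutrophil collagenase gene, measured 20.0 ± 12.8 and 9.91 ± 5.39 CPM. The 10 eosinophil markers (median 0.11, mean −0.03, adjusted p = 0.499) and the 20 basophil and mast cell markers (median 0.13, adjusted p = 0.261) did not pass either. Plasma cell (10 measured, median 0.07, mean 0.14, adjusted p = 0.570), macrophage (13 measured, median −0.05, mean −0.15, adjusted p = 0.451) and stromal and endothelial markers (15 measured, median 0.07, mean −0.07, adjusted p = 0.844) did not pass. Several of these lists were called when a single pool was left out. The erythroid median was then −0.18 without RUX pool 6, and 0.20, 0.22 and 0.13 without untreated pool 2, RUX pool 4 and RUX pool 5. The neutrophil median was −0.28 and −0.35 without untreated pool 1 and RUX pool 4, and 0.20 and 0.02 without untreated pool 3 and RUX pool 6. Without untreated pool 3 the eosinophil and basophil medians were 0.91 and 0.25, and without RUX pool 6 the basophil and stromal medians were 0.31 and 0.09.

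Proliferation, growth and stress genes gave no list that passed. The 50 S-phase and DNA replication genes had a median of −0.03 (20 positive, 30 negative; camera adjusted p = 0.348) and the 49 G2/M and mitosis genes one of −0.01 (22 positive, 27 negative; adjusted p = 0.634). Prim1, a DNA primase gene, measured 155 ± 29.2 and 132 ± 7.13 CPM, and Plk1, a mitotic kinase gene, 63.1 ± 1.14 and 74.0 ± 17.8 CPM. Both cell cycle lists passed on the lower side without RUX pool 6 (medians −0.09 and −0.12, adjusted p = 0.00123 and 0.000862). The 78 cytosolic ribosomal protein genes (median 0.08, adjusted p = 0.0824) and 75 nuclear-encoded oxidative phosphorylation genes (median 0.04, adjusted p = 0.181) were highest in untreated pool 3 and RUX pool 4, the pools apart on the first principal component, and passed on the lower side without RUX pool 4 (medians −0.14 and −0.09). They passed on the higher side without untreated pool 3, RUX pool 5 or RUX pool 6 (medians up to 0.20 and 0.15). Cholesterol synthesis genes (25 measured, median 0.11, mean 0.06, adjusted p = 0.268), integrated stress response and unfolded protein genes (31 measured, median 0.05, mean 0.02, adjusted p = 0.348), p53 targets (30 measured, median −0.09, adjusted p = 0.357) and BCL2-family regulators (16 measured, median −0.08, adjusted p = 0.451) did not pass. The 27 immediate early and heat shock genes had a median of 0.05 and a mean of 0.01 (adjusted p = 0.634), and passed on the lower side without untreated pool 1 (median −0.08) and on the higher side without untreated pool 3 or RUX pool 6 (medians 0.08 and 0.08).

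Transcripts of the sort antigens were as follows, in CPM of the whole library. Kit, the gene of the sorted receptor, was at 191 to 476 CPM in the 6 pools, with its lowest value in untreated pool 3 and a log2 fold change of 0.06 ± 0.26 (SE; adjusted p = 1). Of genes for lineage antigens, Cd3e was at 0.103 to 0.543 CPM, Cd4 at 0.543 to 1.72 CPM and Cd8a at 0 to 0.241 CPM. Itgam was at 11.3 to 16.7 CPM in the 6 pools. A count of 0 allows up to 0.0615 to 0.110 CPM, depending on the depth of the pool. The pools were labelled female, and in all 6 the Y-linked genes Eif2s3y (77.1 to 122 CPM), Ddx3y (66.7 to 93.8 CPM), Uty (25.5 to 52.1 CPM) and Kdm5d (14.6 to 22.9 CPM) were counted, while Xist, the RNA that coats the inactive X chromosome of female cells, was at 0.284 to 0.877 CPM. These sex-linked genes were chosen after their values were seen.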

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

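Tests without untreated pool 3 and RUX pool 4, with 1 surrogate variable and without Lars2 and Rn45s were chosen after the results were seen. The count of 0 genes at an adjusted p under 0.05 held in 18 of 20 alternatives for genes; it was 14 without the low-count filter (19186 genes tested) and 1 with limma-voom quality weights, and the cause was not tested. No scaling moved the median of all genes by over 0.1. Of the genes named by the rule, 3 were called in an alternative, Mmp8, Mmp9 and Prss34, each without the low-count filter.

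The count of 7 lists (3 higher, 4 lower) fell to 4 with quality weights (4 higher, 0 lower: all 4 lower calls ended, at adjusted p = 0.275 to 0.648) and to 0 with an estimated correlation and with fry, which allow for genes of a list varying together; it ran from 5 to 13 when each pool was left out (11 without RUX pool 4, 13 without RUX pool 6) and from 5 to 10 elsewhere. With the estimated correlation and fry, medians of the interferon list (0.22) and the stem cell list (0.222) are those of the same fit and only the call was lost. Over all alternatives the interferon list kept its direction, with medians of 0.163 to 0.259 when pools were left out. The stem cell median was 0.063 (adjusted p = 0.134) without untreated pool 3 and RUX pool 4, and 0.065 to 0.304 with each pool left out.

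With the surrogate variable, which was 0.903 in RUX pool 6 and −0.287 to −0.093 in the others, STAT5/STAT3 targets (0.07), S-phase genes (−0.082) and G2/M genes (−0.106) were called, and erythroid markers reversed to −0.152. Ribosomal proteins (0.149), oxidative phosphorylation (0.091) and basophil markers (0.242) were then also called, and all 4 lower calls ended (adjusted p = 0.390 to 0.892), for 7 lists higher and 3 lower. Without untreated pool 3 and RUX pool 4 eosinophil markers were called at 0.691 (0.109 over all pools), erythroid markers at 0.151 and neutrophil markers at 0.147, against −0.075 over all pools; quality weights gave 0.289 for the last. The cause was not tested, except that fewer pools entered where pools were left out. Ranges with each pool left out were −0.069 to 0.082 for STAT5/STAT3 targets, −0.092 to 0.017 for S-phase, −0.121 to 0.052 for G2/M and −0.175 to 0.219 for erythroid genes. They were −0.142 to 0.202 for ribosomal proteins, −0.091 to 0.151 for oxidative phosphorylation, −0.076 to 0.08 for immediate early genes, −0.346 to 0.196 for neutrophil, −0.276 to 0.01 for monocyte and dendritic, and −0.104 to 0.226 for stromal markers. Of genes at 5 CPM or more, 98.3% had a fold interval within 2-fold, against 80.9% of all tested genes, so low counts limited the precision of the rest.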

Other observations

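S100a8 and Camp, 2 granulocyte transcripts picked after their values were seen, differed between untreated pools by more than 10-fold, while Mmp8 ran from 5.75 to 30.5 CPM and the fixed neutrophil list from −0.95 to 0.94 in mean deviation. S100a8 was at 54.5, 609 and 739 CPM in untreated pools 1, 2 and 3 and at 497, 254 and 111 CPM in RUX pools 4, 5 and 6. Camp, which encodes the neutrophil peptide cathelicidin, was at 12.5, 202 and 209 CPM in the untreated and 130, 77.3 and 24.2 CPM in the RUX pools. Ngp and Lcn2, both of neutrophil granules, had their lowest values in untreated pool 1 (33.5 and 5.18 CPM) and RUX pool 6 (82.5 and 12.3 CPM). Genes with the most negative loadings on the first component included Sptb, the erythroid spectrin gene, at 14.7 CPM in RUX pool 4 and 62.5 CPM in RUX pool 6.

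Tests of the other splits of the pools, of shared variation and of RUX pool 5 for the interferon list, of ribosomal RNA and granulocyte markers for the pool axis were chosen after the results were seen. Splitting the 6 pools 3 against 3 in all 10 ways gave a highest count of 5 genes among the other splits, against 0 for the treatment. For lists the real count was 7 and the highest other 12, with 8 of the 10 splits at 7 or more. The split of untreated pools 1 and 2 and RUX pool 6 against the rest called Prtn3, Prg2, Prg3, Cebpb and Hp and had 1810 genes at an unadjusted p under 0.05, against 254 for the treatment, which points to a structure of the pools other than treatment. These 10 splits are too few for a share under 0.05.

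The higher interferon list under RUX is a candidate for follow-up, since JAK1 relays interferon signals and its inhibition acutely lowers these genes. Without RUX pool 5, the highest pool, the list's median was 0.188, which argues against that pool as the whole cause of the shifted median. The camera adjusted p of 0.000384 there used the preset correlation, which makes little allowance for genes varying together. The median over all pools lay at percentile 100 of random lists matched on expression and exon length. Random genes need not vary together as those of the list do, so this comparison speaks only to expression and length. Genes of the list varying together between pools may account for the call, as the adjusted p was 0.641 with an estimated correlation. Only 1 of the 10 splits, the real one, had a camera p as small (4.98e-10; −log10 of the next 4.58), as for the stem cell list (1 of 10; 4.06e-08; −log10 of the next 6.41), and 10 splits cannot give a share under 0.05. An effect of treatment stays open, untested beyond these data.

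The axis that sets untreated pool 3 and RUX pool 4 apart does not follow treatment. Ribosomal RNA carry-over stays open. The ranks of their Lars2 and Rn45s shares sum to 9, where 3 to 11 is possible. The share was 2.086% in untreated pool 3 and highest, 6.249%, in RUX pool 4. Most of it was Lars2 (1.812 and 5.213%), whereas only Rn45s is a ribosomal RNA precursor. Rn45s alone was at 0.274% in untreated pool 3 and highest, 1.036%, in RUX pool 4. Loadings correlated across genes with exon length (Spearman's rho = −0.498; genes are not independent replicates), so that shorter genes were higher in these pools, and RNA quality or fragment selection may contribute. The correlation with GC content (0.158, for 96.3% of the tested genes) lies between the bounds set for and against it, so GC content stays open. Neutrophil markers had a median loading at percentile 100 of matched random lists. That test was chosen after members of the list were seen among the highest loadings, so it restates that observation. A larger share of neutrophil lineage cells in some pools may also contribute, and the stage of such cells was not tested. S100a8 and Camp were high in untreated pool 2 as well, which lies at the other end of the axis.

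Y-linked transcripts with low Xist appeared in all 6 pools labelled female, in both treatments alike. Loss of Xist reads to overlapping Tsix is argued against, as 10.9% of Xist exon bases overlap another gene in the counting annotation. A small minority of male cells is argued against by the Y-to-X count ratios, with medians over pools of 0.278 for Ddx3y to Ddx3x, 1.57 for Eif2s3y to Eif2s3x and 0.26 for Kdm5d to Kdm5c. In all 6 pools the Y-linked genes stood at 14.6 (Kdm5d) to 122 CPM (Eif2s3y) and Xist at 0.284 to 0.877 CPM. These values argue against female cells as the main source of the RNA. Male mice, which the labels contradict, are a candidate explanation, from the ratio of 0.26 and the low Xist. Beyond these checks of counts no biological explanation was tested, since the design names no second sex.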
